A study of Homo sapiens with 14 samples.

How the data were processed

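MicroRNA levels were measured in MKN74 cells, an established human gastric cancer line, and in tumours that MKN74 cells formed under the skin of mice. Per the labels, total RNA was labelled with the dye Hy5 and hybridised to a custom 1-colour miRNA array. The cultures had no metformin or 10 mM metformin for 72 h. Treated mice had metformin injected into the abdomen 5 times a week for 4 weeks at 1 or 2 mg per animal and day. The labels do not say which tumour had which dose, so the treated tumours were kept as 1 group. They also do not say whether replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

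The values deposited by the authors are linear spot intensities, with a blank where no value is listed. The table has 1001 rows, against 985 human probes stated per the labels' design text. Between 94 and 442 probes had a value on an array, 251 had none on any array and 76 had one on all 14. The scanner, the software and the rule that left a cell blank are not given in the sources used here. On 7 arrays every value, or 100%, lay on a grid with a step of 0.5. On the other 7 arrays at most 29.9% did. Their values below 60 followed a grid with another step, with a concentration of 0.780 to 0.952, where 1 is a perfect grid and 200 draws of values off any grid gave at most 0.468. Multiplication of each of these arrays by a factor, between 0.53 and 1.14, would give such steps if the original step was 0.5, and these factors were used where factors are divided out. Factors were carried by both arrays of culture replicates 3 and 4 and by all 3 treated tumour arrays, and by none of the control tumour arrays. What the factors scale to is not given in the sources used here, and array medians still differed. No 2 arrays shared more than 2.45% of their values. Signal over background and spot-level error were not analysed here, so the number of arrays limits the precision.

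Values were put on the log2 scale and quantile normalised within each comparison. The mapping was taken from the probes listed on every array of the comparison, a choice made after the extent of blank cells was seen. Quantile normalisation gives probes of equal rank equal values, so a probe that ranks first on each array has a change of 0 and an SD of 0 by construction, and for the probe that did so, MIMAT0009449, deposited intensities are given. A rank that stays equal within a group likewise shrinks a probe's SD there, and with it the SE and p. Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg), called at an adjusted p below 0.05. A probe entered with values on at least 2 arrays of each group, and blank cells were left out. The comparisons were metformin against control in cultures and in tumours, the difference between these 2 changes, their correlation across probes, and control tumours against control cultures. The last of these had been planned only for values on a common scale, and it was run after the quantile step had placed the arrays on 1 scale. Array measures were compared by exact two-sided permutation tests, and within same-numbered pairs by exact two-sided sign-flip tests, a form of permutation.

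Each comparison was tested on simulated data with the real means, spread, blank cells and array offsets, in 50 simulations per setting. With no probe changed, false calls appeared in 1 of 50 simulations for the cultures, 1 for the tumours, 2 for the difference of changes and 2 for tumours against cultures. With probes changed, the quantile step itself produced false calls. With 60 of 159 culture probes changed, 24.3% of the calls were false, against 4.45% when arrays were centred on a median instead. With 12 of 159 changed the shares were 11.5% and 7.49%. For the 253 tumour probes they were 4.40% and 7.14% with 12 changed, and 7.41% and 4.33% with 60 changed. For the 149 probes of the difference they were 10.7% and 4.57% with 12 changed, and 16.6% and 3.76% with 60 changed. For the 176 probes of tumours against cultures they were 25.6% and 8.40% with 12 changed, and 21.3% and 5.03% with 60 changed. The simulated arrays differed only by an offset, which favours the median. Quantile normalisation had been chosen before the data were examined and was kept. The calls can therefore hold more false ones than the nominal 5%, as in all of these settings except the tumours with 12 probes changed. Median-centred counts are given below for the tumours, over all listed probes, and for tumours against cultures. With 12 probes changed, 4-fold changes were recovered in 50.5% of cases in the cultures, 45.0% in the tumours, 17.5% for the difference and 47.5% for tumours against cultures, and 8-fold changes in 64.0%, 82.0%, 43.5% and 67.0%.

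The labels number the replicates alike in control and treated groups. Deviations from the group means correlated between same-numbered arrays at 0.33, 0.23, 0.28 and 0.43 across 78 probes in the cultures and at 0.23, 0.16 and 0.39 across 182 probes in the tumours, and each array correlated best with its own number. The numbers were therefore taken to pair the samples, and a fit with the replicate number as a block was run as an alternative.

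Rows carry miRBase accessions, and 5 rows carry several. The human gene table used here, of assembly GRCh38.p14, held 0 of these accessions, so no row was given a miRNA name. The 26 miRNA lists and the cell type markers fixed before the data were examined could not be matched, and their tests were not run. The rule fixed beforehand named probes by the smallest p in each direction, or by the largest change among called probes, plus the 3 probes with the highest mean. Because the rows have no names, it was limited to 2 identifiers per direction in each comparison. Alternatives covered scaling, filters, blank cells, variance models, array weights, thresholds, the block and leaving out each array.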

Results

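The series measured miRNAs in MKN74 gastric cancer cells with and without metformin, an antidiabetic drug, in culture and as tumours in mice. There were 4 control and 4 metformin-treated cultures, and 3 control and 3 metformin-treated tumours, each on 1 array. The title of the series places the question in the anti-tumour effect of metformin. Probes are given by their miRBase accession.

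Control cultures had values for 158, 94, 213 and 364 probes and treated cultures for 168, 162, 188 and 145. Control tumours had values for 420, 419 and 442 probes and treated tumours for 307, 283 and 324. The mean in treated tumours was 305 ± 20.6 (SD, n = 3) against 427 ± 13.0 (SD, n = 3) in controls, with an exact permutation p of 0.1, the smallest that 3 against 3 arrays can give. Within same-numbered pairs the treated tumour array listed fewer probes than the control array in all 3, with differences of -113, -136 and -118 (exact sign-flip p = 0.25, the smallest that 3 pairs can give). In the cultures the means were 166 ± 17.7 and 207 ± 115 (SD, n = 4 each, exact permutation p = 0.686), and the pairs differed by 10, 68, -25 and -219 (exact sign-flip p = 0.75). One probe, MIMAT0009449, was the brightest on every array. As deposited it measured 52336 ± 19287 units in treated and 32721 ± 6651 in control cultures (SD, n = 4 each), and 28459 ± 10132 in treated and 43570 ± 12439 in control tumours (SD, n = 3 each). It took 53.1% ± 6.67 of the summed intensity in control cultures and 50.3% ± 9.0 in treated ones (SD, n = 4 each, exact permutation p = 0.686). In control tumours it took 27.8% ± 2.22 and in treated ones 20.5% ± 4.91 (SD, n = 3 each, exact permutation p = 0.2). Its share was lower in control tumours than in control cultures (exact permutation p = 0.0286, the smallest that 4 against 3 arrays can give).

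**Figure D1:**
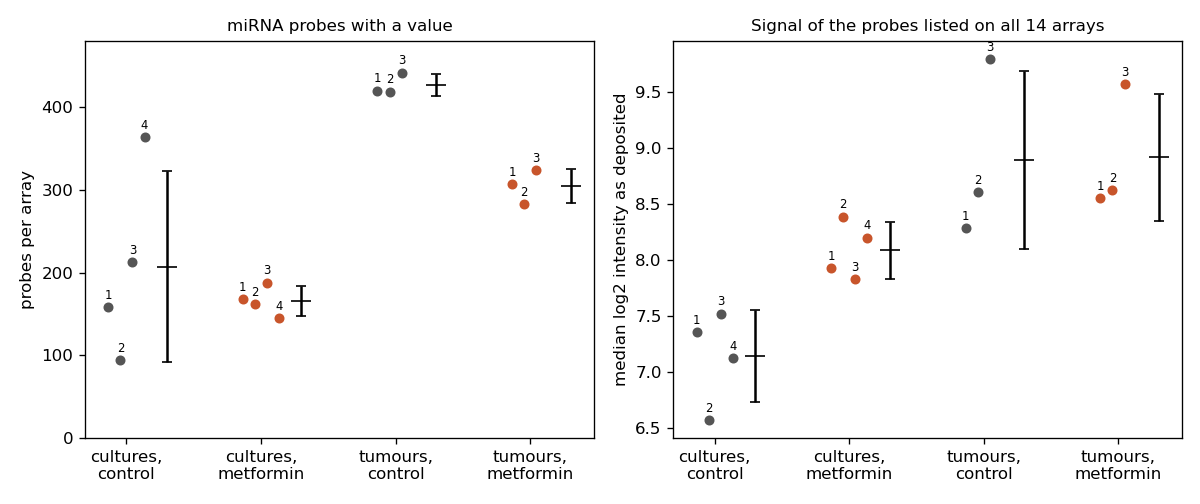
Each point is 1 array, marked with its replicate number; bars show the mean and SD of each group. The left panel counts the probes with a value, and the right panel gives the median log2 intensity, as deposited, of the 76 probes listed on all 14 arrays. The treated tumours list 283 to 324 probes, all below the control tumours at 419 to 442.

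Treated cultures were brighter than control cultures in the values as deposited. The median log2 intensity of the 78 probes listed on every culture array was 7.99 ± 0.30 with metformin and 7.06 ± 0.42 without (SD, n = 4 each), a difference of 0.93 (exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give). The pairs of same-numbered arrays differed by 0.51, 1.88, 0.29 and 1.04 (exact sign-flip p = 0.125, the smallest that 4 pairs can give). With the array factors divided out the difference was 0.60 (exact permutation p = 0.143). The pairs then differed by 0.51, 1.88, 0.10 and -0.08 (exact sign-flip p = 0.25), so pair 2 carried most of it. In the tumours the median over the probes listed on every tumour array was 6.94 ± 0.57 with metformin and 7.07 ± 0.64 without (SD, n = 3 each), a difference of -0.13 (exact permutation p = 0.7), and the pairs differed by 0.01, -0.21 and -0.19 (exact sign-flip p = 0.5). The difference between both changes was -1.06 as deposited (exact permutation p = 0.0886, or 0.0571 when whole pairs were exchanged) and -0.41 with the factors divided out (exact permutation p = 0.503, or 0.6 when whole pairs were exchanged).

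The effect of metformin on single miRNAs in cultured MKN74 cells was compared over 159 probes, and limma called 0 of them. At an unadjusted p below 0.05 there were 8, of which 3 had higher and 5 lower values with metformin, where 7.95 are expected by chance. The smallest adjusted p in limma was 0.339. Intensity units here and below are as deposited, while pairs of named probes and log2 differences are after normalisation unless said otherwise. Treated culture arrays were brighter by 0.93 in the median log2 intensity as deposited, so a contrast in units also holds array brightness. The values of MIMAT0006766 were higher with metformin in all 4 pairs, at 4432 ± 4056 against 590 ± 338 intensity units (SD, n = 4 each), with a log2 difference of 1.88 ± 0.62 (SE) and an adjusted p of 0.744 in limma. MIMAT0000692 was also higher in all 4 pairs, at 92.8 ± 33.9 against 31.2 ± 10.2 units (SD, n = 4 each), with a log2 difference of 0.72 ± 0.28 (SE) and an adjusted p of 0.754. The lower normalised values were those of MIMAT0004497, with a log2 difference of -0.81 ± 0.18 (SE, n = 4 each, limma adjusted p = 0.339), and MIMAT0010131, with -1.39 ± 0.39 (SE, n = 4 and 3, limma adjusted p = 0.732). None of these 4 differences passed the threshold in the main fit. These probes had been named for their small p, so agreement across the pairs is no separate support. MIMAT0006766 was called as deposited (limma adjusted p = 0.00680) and with the factors divided out as well (limma adjusted p = 0.0270), and MIMAT0000692 as deposited (limma adjusted p = 0.0442). MIMAT0004497 was lower in all 4 pairs after normalisation, but its deposited intensities were 41.1 ± 16.7 with metformin and 38.6 ± 12.5 without (SD, n = 4 each), a log2 difference of 0.04. It was the 1 probe called when only the 78 probes listed on every culture array were tested (limma adjusted p = 0.00860). In the values as deposited, 8 probes were called, all higher, on arrays whose median change was 0.67, and none with replicates as a block.

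The same comparison in MKN74 tumours covered 253 probes, and limma again called 0. At an unadjusted p below 0.05 there were 16, with 9 higher and 7 lower in treated tumours, against 12.65 expected by chance. The smallest adjusted p in limma was 0.332. MIMAT0002809 measured 112 ± 64.8 intensity units in treated and 43.3 ± 21.2 in control tumours (SD, n = 3 each), a log2 difference of 1.56 ± 0.38 (SE). MIMAT0000753 measured 97.4 ± 45.6 against 34.8 ± 10.8 units (SD, n = 3 each), a difference of 1.69 ± 0.43 (SE). Lower values were found for MIMAT0004911, at 13.5 ± 2.59 against 41.8 ± 12.6 units (SD, n = 3 each) and a difference of -1.24 ± 0.32 (SE), and for MIMAT0009453, at 158 ± 18.3 against 652 ± 308 units (SD, n = 3 each) and a difference of -2.03 ± 0.54 (SE). The treated values of MIMAT0004911, 10.6 to 15.6 units, lay near the lowest listed ones on treated tumour arrays, which were 8.7 to 12.9. All 4 had an adjusted p of 0.332 in limma and did not pass in the main fit. Each kept its direction in all 3 same-numbered pairs after normalisation, but these probes had been named for their small p. Scaling to all listed probes, which are fewer on treated arrays, gave 4 lower probes by median centring and 17 by quantile normalisation, with a median change of -0.78 and -0.75. With replicates as a block these counts became 32 and 0. MIMAT0004911 and MIMAT0009453 were among the calls by median centring over all listed probes (limma adjusted p = 0.0142 and 0.00684, and 0.0010 and 0.000147 with the block) and by quantile normalisation over all listed values without the block (limma adjusted p = 0.0452 for both).

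Few of these estimates were precise enough to bound an effect. The 95% confidence interval of the change lay within a 2-fold range for 36 of 159 probes in the cultures and for 42 of 253 in the tumours. The median SE of a log2 change was 0.47 in the cultures and 0.42 in the tumours. These intervals and SEs came from the fit without the replicate block.

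Whether metformin acted alike in both settings was tested directly over 149 probes. Limma called 0 of them for a difference between the tumour and the culture change, with 5 at an unadjusted p below 0.05 against 7.45 expected, and a smallest adjusted p of 0.826. The tumour change exceeded the culture change by 1.25 ± 0.37 (SE) for MIMAT0000256 and by 2.22 ± 0.79 for MIMAT0000072 on the log2 scale. It was below the culture change for MIMAT0006766, by -2.58 ± 1.00 (SE), and for MIMAT0009453, by -2.05 ± 0.97. All 4 had an adjusted p of 0.826 in limma. Across the 149 probes the changes in cultures and in tumours, which share no samples, correlated at r = -0.045 (exact permutation p = 0.743) and rho = -0.034 (exact permutation p = 0.760), with a Benjamini-Hochberg adjusted p of 0.760 for both. Probes are not independent replicates, so p came from relabelling the arrays, without keeping same-numbered pairs together. The changes had the same sign for 68 probes, or 45.6%.

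**Figure D2:**
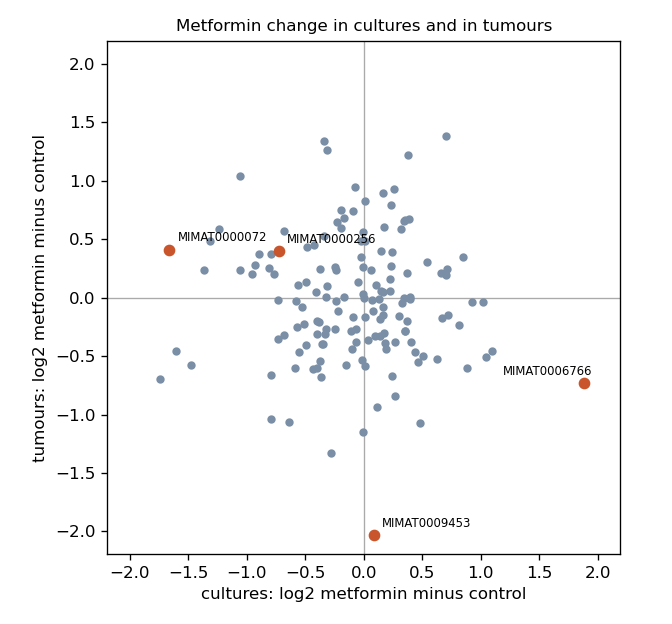
Each point is 1 of 149 probes, with its log2 metformin change in cultures on the horizontal axis and in tumours on the vertical axis, after quantile normalisation. Labelled points are the 4 probes named for the difference between both changes; none passed the threshold, and the correlation was -0.045.

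Control tumours were compared with control cultures as background, since a tumour also holds mouse cells and the kind of sample cannot be told apart from any separate array run. Of 176 probes, limma called 16, of which 12 were higher and 4 lower in tumours relative to the other probes. MIMAT0000724 was at 3632 ± 1340 intensity units in tumours (SD, n = 3) and 24.5 ± 10.9 in cultures (SD, n = 4), a log2 difference of 5.28 ± 0.27 (SE, limma adjusted p = 1.89e-05). Its equal rank gave it the same normalised value on all 3 control tumours, an SD of 0 by construction. This SE and p therefore leave out its spread between tumours. It was called in all 17 alternative settings, the values as deposited among them. MIMAT0000267 was at 400 ± 98.4 units in tumours and 11.6 ± 4.52 in cultures (SD, n = 3 each), a difference of 3.62 ± 0.40 (SE, limma adjusted p = 0.00373). MIMAT0000087 was lower by normalised values, with a difference of -2.42 ± 0.24 (SE, limma adjusted p = 0.00114), as was MIMAT0000075, with -2.00 ± 0.45 (SE, limma adjusted p = 0.0358). MIMAT0000087 was called in 14 of 17 settings and MIMAT0000075 in 8 of 17, and MIMAT0000075 was lost when any 1 array other than control culture 4 was left out. Both were lost as deposited and in both scalings over all listed probes. The lower calls are relative to the other probes, because tumour arrays were brighter by 1.75 in the median log2 intensity of the 76 probes listed on all 14 arrays. As deposited, MIMAT0000087 was at 154 ± 119 units in tumours (SD, n = 3) and 194.9 ± 63.5 in cultures (SD, n = 4), MIMAT0000075 was at 172 ± 119 and 146 ± 88.0, and 115 probes were called, all higher, with a median change of 1.77. Median centring over probes listed on every array called 25 probes, 17 higher and 8 lower, among them all 16. Median centring over all listed probes called 64 and quantile normalisation over all listed values 24, all higher in both. Filling blank cells with each array's lowest value called 35 probes, 29 higher and 6 lower, and the 80 probes listed on every array gave 14, 5 higher and 9 lower.

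The count rested on single arrays. It was 7, 8 and 26 without control culture 1, 3 and 4, and 4 and 3 without control tumour 1 and 2. The same contrast was made on the treated arrays. These are other arrays, but same-numbered control and treated arrays deviated together, so the 2 sets are not independent. On the treated arrays limma called 14 of 165 probes, 7 higher and 7 lower. Across 149 probes tested in both sets, the tumour-minus-culture differences correlated at r = 0.77 and rho = 0.70. Of the 16 called probes, 15 were tested on the treated arrays, all 15 had the same sign there and 7 were called there. Of all 149 probes, 74.5% had the same sign in both sets.

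**Figure D3:**
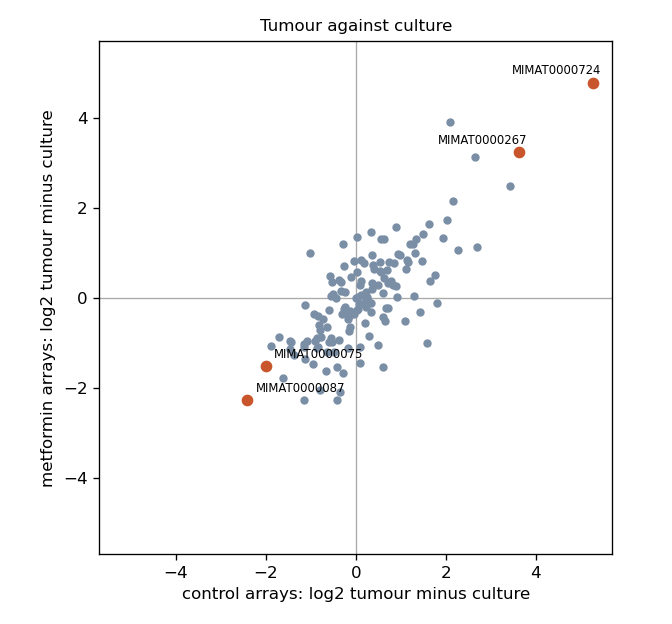
Each point is 1 of 149 probes, with the log2 difference of tumours minus cultures on control arrays on the horizontal axis and on metformin arrays on the vertical axis, after quantile normalisation. The 4 labelled probes are those named for control tumours against control cultures, and all 4 have the same sign on both axes; r was 0.77.

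Blank cells gave a further contrast between tumours and cultures. There were 17 probes with values on all 6 tumour arrays and on none of the 8 culture arrays, and 0 with the reverse pattern. The reverse pattern had few candidates, since 76 of the 78 probes listed on every culture array were listed on all 14 arrays. Control culture 2 listed only 94 probes, and control tumour arrays were brighter than control culture arrays. The imbalance can therefore follow from how many probes the arrays listed, and it does not by itself show a difference between the kinds of sample. The lowest listed signal on the culture arrays, normalised with the tumours, was used as a floor, which takes a blank cell to mean a signal below it. This may not hold, since treated culture 4 listed fewer probes than control culture 4 although its lowest listed intensity was lower. The margins that follow are therefore over the floor and are not firm bounds on a difference. Against the mean floor of the 8 culture arrays, the mean of the 6 tumour arrays was at least 2-fold higher for 9 of the 17 probes and at least 4-fold higher for 6. Against the highest floor of any culture array these counts were 6 and 3. The largest margin was 19.5-fold over the mean floor and 8.63-fold over the highest.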

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

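Of the tests weighed in this part, those on the lowest listed intensity, on a general loss or rise of signal and on the array factors were chosen after the result was seen.

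MIMAT0006766 was higher with metformin in all 4 culture pairs and lower in all 3 tumour pairs, so that the mean change differed by -2.62 on the log2 scale. In the limma fit the difference was -2.58, with an adjusted p of 0.826. The probe had been named for its small p, so agreement across the pairs is no separate support. MIMAT0004810 had values on all 3 treated tumour arrays, 16.4 intensity units on average, and on no control tumour array, and so entered no tumour comparison. It was the 1 probe with this pattern, against 20 with the reverse. Its values of 11.1 to 19.1 units lay near the lowest listed ones, which were 8.7 to 12.9 on treated and 13.5 to 14.9 on control tumour arrays. Of 30 sets of 4 culture arrays examined, 2 held an array far from the rest, about the 1 in 20 that chance gives. These were the treated cultures for MIMAT0000256, where the gap to the nearest array was 0.863 of the range, and for MIMAT0000087, where it was 0.919.

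Treated tumours listed fewer probes. A higher intensity limit would raise the lowest listed intensity on treated arrays, which with factors divided out was lower than on control arrays by a mean difference of -1.60 units. The rule that left cells blank is not given, so a stricter rule of another kind stays open. In culture pair 4 the lowest listed intensity did not follow the listing. Treated culture 4 listed 145 probes down to 5.33 units, and control culture 4 listed 364 down to 11.98, with factors divided out. A general loss of signal would need a log2 shift of about -0.46, while the probes listed on all 6 arrays shifted by 0.19 ± 0.16 (SE over 3 pairs), or by -0.13 ± 0.07 as deposited. This cannot exclude a general loss, because 3 pairs leave a wide interval. The probes compared also leave out those lost on treated arrays. Of 72 probes listed on at least 2 control and no treated tumours, 94.4% averaged under 2 times the lowest listed intensity, against 46.3% of all 395 probes on at least 2 control tumours, so the loss may be one of dim signal near the limit, although any loss of probes would take dim ones first. Since every treated and no control tumour array carries a factor, metformin, the listing rule and the handling of the arrays stay open.

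Treated cultures were brighter as deposited. For pair 4 the factors are a candidate cause, since its shift was -0.084 once they were divided out. Pairs 1 and 2 carry no factor and shifted by 0.51 and 1.88, or 1.19 on average, a mean carried by pair 2, which holds the dim control 2. Without the dim control 2, 0 probes were called as deposited, which is what had been written beforehand as the sign of that array being the cause, but 0 were also called without control 4 or treated culture 2. The shift was not the sign written beforehand. As deposited without control 2 it stayed at 0.65 (exact permutation p = 0.0286), which argues against that array alone as the whole cause. That shift still holds the factors. With factors divided out, controls 1, 3 and 4 had medians of 7.34, 7.68 and 8.02, and the treated cultures 7.84, 8.34, 7.77 and 7.93. These overlap, so control 2 and the factors together are not argued against. A general rise with metformin cannot be told apart from chance with the factors divided out (exact permutation p = 0.143).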

How the results depend on the processing

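Settings that used the values as deposited, median centring over shared probes, filled blank cells or divided-out factors, those that joined a scaling with the block, and all for tumours against cultures were chosen after the data were seen. In the cultures limma called 0 probes, against 8 as deposited, 1 with factors divided out, 1 with only probes on every array and 8 at an unadjusted p. In the tumours it called 0, against 4 with median centring over all listed probes, 32 when the block was added to that, 17 with quantile normalisation over all listed values and 16 at an unadjusted p. For the difference of changes it called 0, against 5 at an unadjusted p. Leaving out any array left all 3 counts at 0. With the replicate number as a block the 3 counts were 0, and the pairing changed no other call than those given for the deposited and all-probe scalings. For tumours against cultures the count of 16 became 115 as deposited, 25 with median centring over shared probes, 64 over all listed probes, 35 with filled blank cells and 44 at an unadjusted p, and ranged from 3 to 26 when an array was left out. Other settings gave counts within 1.5 times. The cause of these moves was not tested, except that all-probe scalings compare arrays with different numbers of listed probes.

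The correlation of both changes had no stable sign. It was 0.015 as deposited, 0.119 with median centring and 0.070 with quantile normalisation over all listed probes, 0.072 over probes on every array, 0.114 without the probes below the median level, and -0.226 to 0.083 when an array was left out, with exact permutation p between 0.111 and 0.971. The shift of the tumour array medians turned to 0.19 with factors divided out and ranged from -0.37 to 0.26 when an array was left out, turning positive at 0.15, 0.11 and 0.26. Among named probes, MIMAT0004497 in cultures turned to 0.040 as deposited, with or without the block, and MIMAT0000075 in tumours against cultures to 0.10 as deposited and 0.15 with median centring over all listed probes. The blank cells limit what can be tested, and the dim signal of many probes may do so as well.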

Other observations

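The tests on signal level, partly listed probes and scaling in this part were chosen after the result was seen, and the pattern itself was noticed in the data.

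The other 2 of the 3 brightest probes were MIMAT0000078 and MIMAT0000080. With arrays centred on a median, their log2 change with metformin was -0.51 ± 0.40 and -0.91 ± 0.42 (SE) in cultures and 0.09 ± 0.44 and 0.18 ± 0.48 in tumours, with limma adjusted p of 0.897, 0.689, 0.974 and 0.957. The brightest probe, MIMAT0009449, changed by -0.32 ± 0.43 and -0.52 ± 0.46, with limma adjusted p of 0.909 and 0.813. Relative to the other probes it was lower in control tumours than in control cultures, by a difference of -1.44 ± 0.43 (limma adjusted p = 0.0347 with median centring), but its deposited intensities were higher there, at 43570 ± 12439 (SD, n = 3) against 32721 ± 6651 units (SD, n = 4), on arrays that were brighter overall.

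In treated tumours the metformin change was lower for probes with high accession numbers (rho = -0.42 across 253 probes, which are not independent). The median change was 0.11 over 120 probes with accession numbers below 1000, 0.15 over 37 with numbers from 1000 up to 4000 and -0.30 over 96 with numbers of 4000 and above, so the lower values lay in the last of these blocks. A trend with signal level is argued against by a partial rank correlation of -0.45, and partly listed probes by -0.52 over the probes listed on all 6 arrays. Over 5 scalings the values were no nearer to 0 than -0.35. The values as deposited and those centred on a median differ only by a constant per array. Such a constant leaves the ranks of changes unchanged for probes listed on every array, so mainly the quantile scalings bear on this. In the cultures, arrays with a factor against those without gave 0.19. These are replicates 3 and 4 against replicates 1 and 2, so the factor cannot be told apart from other differences between replicates. In the tumours every treated and no control array carries a factor, so the handling of the arrays is not argued against. All 3 pairs were negative, from -0.53 to -0.028, as an effect of metformin would need, although 1 of them hardly differed from 0. In the cultures the value was -0.090 (rho, with 24 of 35 splits as far from 0, and pairs 3 and 4 at 0.16 and 0.023), and the difference from the tumours was not tested. Further, 2 of the 10 splits of the 6 arrays were as far from 0 (0.42 for the real split and 0.43 for the highest other), too few splits for a share under 0.05. Chance, an effect of metformin in the tumours, the handling that put a factor on arrays and an unrecorded array run all stay open.

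Other splits of the same arrays bear on the counts of calls. Where the real count is 0, every split reaches it by construction, so the 35 of 35 splits in the cultures (highest other 2), the 10 of 10 in the tumours (highest other 0) and the 100 of 100 drawn for the difference of changes (highest other 2) say nothing about chance. At an unadjusted p, 17 of the 35 culture splits gave at least the 8 probes of the real one, the highest other 34, so chance cannot be excluded for those 8. A split with 34 may reflect a structure among the culture arrays, which was not tested. Among the 8 splits that part every pair, the others gave 1 to 27. In the tumours 5 of 10 splits gave at least the real 16 at an unadjusted p, the highest other 25, and 10 splits are too few for a share under 0.05. Among the 4 tumour splits that part every pair, the others gave 6 to 10. For control tumours against control cultures only the real 1 of 35 splits called as many as 16, the highest other 6. That is the smallest share that 35 splits can give. Every other split mixes tumours with cultures in at least 1 group, which widens the spread and can lower its count. The splits therefore weigh against chance only to that share and do not exclude it. Nor do they exclude an array run that goes with the kind of sample.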
